A study of Drosophila melanogaster with 6 samples.

How the data were processed

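RNA was profiled on 1-colour Drosophila oligonucleotide arrays in 6 samples. Per the labels, 3 samples (GSC 1 to 3) were germline stem cells purified from bam mutant ovaries, and 3 samples (Kc 1 to 3) were Kc cells, a Drosophila line kept in tissue culture. Samples from Dpp-overexpressing ovaries, which the design also names, were not analysed here. The RNA was labelled with the Enzo BioArray transcript labelling kit, per the labels.

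The authors deposited 1 intensity per probe set and array on a linear scale, and MAS5 is the tool named in the submitters' processing notes. Its version and settings are not given in the sources used here. The deposited table held 14010 probe sets, with no missing value and no detection call. The mean signal after removing 2% of the values at each end was close to 500 on all 6 arrays, which shows a global scaling by the authors, so no second normalization was applied. Every column of the table belonged to a sample, leaving 0 columns with no sample. The number of arrays limits the precision, and signals near the low end have no stated background level to be set against.

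The 44 array control probe sets were left out of the tests, which left 13966. The platform annotation gave 1 gene symbol for 12443 of these, several for 327 and none for 1196. Of those with 1 symbol, 12394 were matched by gene identifier to the RefSeq gene table of the assembly Release 6 plus ISO1 MT, which changed 0 symbols, and 49 kept the platform's symbol. No gene was named from a probe set with several symbols. The array measured 10844 genes, 1209 of them with more than 1 probe set. A gene was represented by its probe set with the highest mean log2 value over the 6 arrays. Of the genes with more than 1 probe set, 418 had at least 1 called probe set. Only 73 had every probe set called the same way, and 11 had probe sets called in opposite directions. In matching the lists, nos and Dl were looked up under their current symbols nanos and Delta, and don was left unmatched because its synonym pointed to another gene.

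Signals were transformed as log2(signal + 38), where 38 is the 25th percentile of all deposited values. Fold changes are on this scale, which understates the change of dim probe sets. GSC and Kc were compared with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with an intensity trend and robust variance estimation, as a two-sided test. P-values were adjusted over all tested probe sets by the Benjamini-Hochberg method. A probe set was called at an adjusted p under 0.05 and a fold of at least 2. Nothing in the labels says that the arrays of a group came from separate cultures or dissections, so p-values measure only the spread between these samples, which may be technical.

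Gene lists with at least 5 measured genes were compared with the other genes by camera with a preset inter-gene correlation of 0.01, and adjusted over the 39 lists tested. A list of transposable elements had 0 measured members and was not tested. Of the 741 pairs of tested lists, 22 share genes, and not all of these are named beside the results. The test, the lists and the rule for naming genes were fixed before the data were examined.

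Genes were named by that rule. It takes the 12 largest folds in each direction among called genes whose groups did not overlap and whose brighter group had a mean signal above the 75th percentile of all values. From each list it takes the 4 called members with the largest absolute folds, the largest called member against the list's majority, and a fixed set of key genes. Genes named outside the rule are said to be so where they appear, apart from wde, cort, don, Cyp1 and Cyp40. These are named only for their place in a list.

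The probe set test was checked on simulated arrays made from the means and residual spread of the 13966 probe sets, with 200 changed. For GSC against Kc it recovered 67% of the 100 probe sets changed by 1.5 on the log2 scale and 82% of the 100 changed by 2, with 1 false call among the unchanged. The real comparison called a larger share, 19.8% of the probe sets, and the adjusted p depends on that share. The simulated noise was also independent between probe sets, so these rates do not carry over to the real comparison.

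Alternatives covered the pseudocount, a floor in its place, quantile normalization, scaling to the median, a filter on dim probe sets, the variance prior, the replicate number as a block, leaving out each array, other fold minimums, treat against a fold of 1.5, the mean over a gene's probe sets, an estimated inter-gene correlation, and fry. Scaling to the 9 hybridisation controls, lists without shared genes, and a restriction to brighter probe sets were added after the data were seen. The order of genes along the chromosomes was taken from the same RefSeq table, and the shuffled orders were drawn with NumPy 2.4.6. Ranges of adjusted p over the alternatives of a list leave out fry, which tests a list against no change and not against the other genes. The rule for the middle probe sets of the control transcripts, with its cutoff, was written when their folds were known, in place of a first rule that asked only for a higher 3' to 5' ratio on all GSC arrays, which the data met but which restated the pattern it was to explain.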

Results

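Gene expression was measured in 2 kinds of Drosophila cells. Germline stem cells (GSC) divide to produce the egg lineage, and in bam mutant ovaries they accumulate because bam, which drives their differentiation, is disrupted. Kc cells are an established line derived from embryos. Each kind was represented by 3 arrays. The comparison asks which transcripts differ between purified stem cells and a cultured somatic line. The authors' scaled signals had array medians between 148.5 (Kc 2) and 176.5 (GSC 1). Across probe sets, log2 signals correlated at 0.967 to 0.977 between GSC arrays, 0.96 to 0.973 between Kc arrays and 0.829 to 0.86 between a GSC and a Kc array, where probe sets are not independent replicates.

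Transcripts of germline genes were among those most above Kc in GSC, and transcripts of some extracellular matrix and hemocyte genes among those most below Kc. Kc cells are the only baseline here, so higher, lower, rose and fell mean relative to Kc. The RNA-binding translational regulator nanos had a signal of 8938 ± 494 in GSC and 29.7 ± 31.6 in Kc (SD, n = 3 each), a log2 fold of 7.14 ± 0.265 (SE, adjusted p = 9.25e-08). A second, dimmer nanos probe set had 1283 against 236.8, a log2 fold of 2.28. The germline RNA helicase vas had 6895 ± 88.9 against 18.5 ± 17.1 (log2 fold 6.98). In the other direction, the clotting factor gene Hml, a marker of hemocytes, had 11.1 ± 7.5 in GSC and 11630 ± 313 in Kc (log2 fold -7.90 ± 0.146, adjusted p = 2.83e-09). The ribosomal protein gene RpS5b reached 30800 ± 3730 in GSC against 637 ± 173 in Kc.

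In all, 1633 probe sets were higher and 1132 lower in GSC, together 19.8% of the 13966 tested. By gene, 1356 were higher and 870 lower among 10844. Folds of at least 16 were found for 46 higher and 79 lower probe sets. Of the called probe sets, 219 carried no gene name, 122 of them higher and 97 lower. The split was 59.1% higher, and it was 80.4% (2821 higher, 688 lower) when arrays were scaled to their hybridisation controls, an alternative chosen after the data were seen that moved the median log2 fold of all probe sets from 0.025 to 0.32. It was 51.6% (1398 higher, 1311 lower) with scaling to the median and 53.7% (1438 higher, 1241 lower) with quantile normalization. The geometric mean signals of the hybridisation controls were 2113, 2884 and 3753 on GSC 1 to 3, and 4302, 3746 and 3636 on Kc 1 to 3. GSC 3 thus lay within the Kc range, and the low values were those of GSC 1 and GSC 2.

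**Figure D1:**
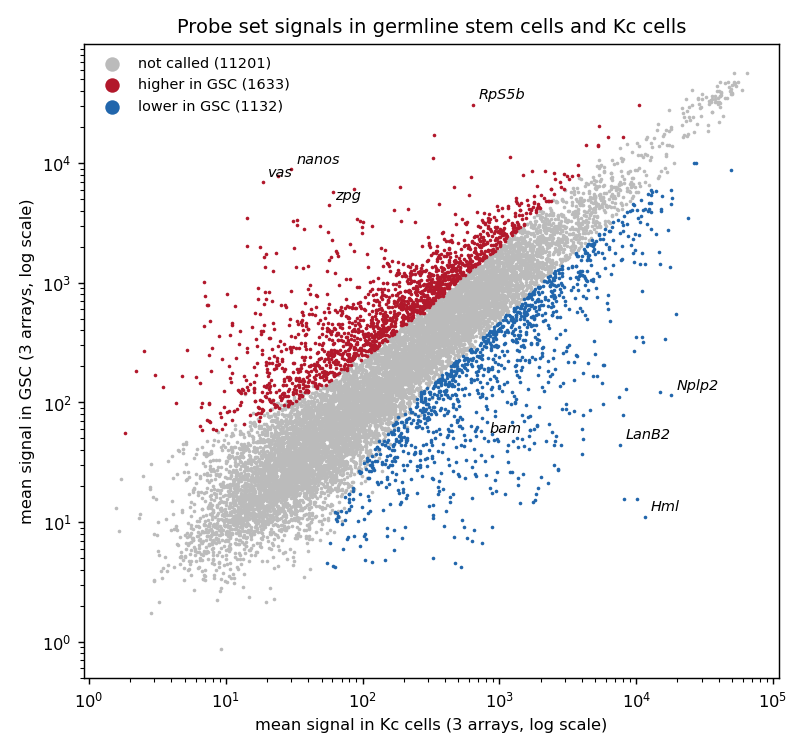
Mean signal of each probe set over 3 GSC arrays (vertical, log scale) against 3 Kc arrays (horizontal, log scale), with probe sets higher in GSC in red (1633), lower in blue (1132) and not called in grey. RpS5b is the brightest of the labelled genes in GSC at 30800, and Hml lies lowest at 11.1 in GSC against 11630 in Kc.

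The mutated gene, bam, had signals of 87, 33.8 and 29.2 on the GSC arrays and 885, 587.7 and 853.7 on the Kc arrays, a log2 fold of -3.25 ± 0.288 (adjusted p = 1.8e-05). Where its probes lie relative to the mutation is not known here, and no ovary with intact bam was compared, so this value does not check the labels.

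Many of the 12 genes with the largest folds upward have known roles in the germline, but which genes these are, and their order, depends on the pseudocount, since several had Kc signals below it. In a comparison chosen after the data were seen, 8 of the 12 upward and 8 of the 12 downward were among the 12 largest with a pseudocount of 1, 10 and 9 with the pseudocount at the median, and 10 and 10 with a floor. Besides nanos and vas these were dhd, a thioredoxin of the female germline (log2 fold 6.09), the translational regulator orb (5.66), piwi (5.63), the germline gap junction gene zpg (5.57), RpS5b (5.54), a paralog of the general ribosomal protein S5 gene, and krimp (5.53), a piRNA pathway gene. The others were Kots (log2 fold 6.98), the arginine kinase gene Argk1 (6.03), Ypel (5.64) and CG6770 (5.53). CG6770 had a signal of 17020 ± 1240 in GSC against 331.8 ± 33.5 in Kc. The 12 largest folds downward held the laminin subunit genes LanB2 (log2 fold -6.60) and LanA (-5.64), the peroxidasin gene Pxn (-5.63), the organic anion transporter gene Oatp58Dc (-7.58), Idgf6 (-7.23), the neuropeptide-like gene Nplp2 (115.5 ± 79.1 in GSC and 18050 ± 1660 in Kc), the lysosomal sulfatase gene Ids (-6.58), sty (-6.24), an antagonist of receptor tyrosine kinase signalling, Karl (-5.93), the glycine methyltransferase gene Gnmt (-5.69) and CG33080 (-5.46), besides Hml. Other probe sets of these genes were called in the same direction with smaller log2 folds, 1.58 for orb, 4.19 for Argk1, -3.14 for Oatp58Dc, and -3.11 and -3.16 for CG33080.

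Germ cell genes were higher in GSC as a group by the test with the preset correlation, a call lost with an estimated correlation. Of 25 measured members, 16 rose, bam alone fell and 8 passed neither way, with the same counts when adjusted over the list alone. The median log2 fold was 2.13. Sxl, the sex determination gene, had a log2 fold of 0.83 ± 0.127 and was below the fold minimum, which it passed with hybridisation control scaling (1.27). A second Sxl probe set had 0.305 (adjusted p = 0.287). The list's shift had an adjusted p of 3.98e-08 by camera, and adjusted p = 0.052 with an estimated correlation, the highest over its alternatives, which reached down to 3.16e-09. The estimate was -0.0122, below the preset 0.01, so the lost call does not show that the members vary together.

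Genes of the piRNA pathway, which silences transposons in the germline, were also higher by that test, a call lost with an estimated correlation. Of 30 measured, 16 rose, 1 fell and 13 passed neither way, with the same counts adjusted over the list alone. Besides piwi and krimp, the largest were the tudor domain gene tej at 2835 ± 254 against 37.5 ± 10.3 (log2 fold 5.26) and the Argonaute gene aub at 6323 ± 542 against 187 ± 59.4 (4.86). The member that fell was squ (log2 fold -1.31, adjusted p = 0.00011), a call that ended with scaling to the hybridisation controls. The median log2 fold was 1.10 (camera adjusted p = 3.98e-08), with adjusted p = 0.052 with an estimated correlation, within a range of 1.1e-08 to 0.052 over the alternatives. The estimated correlation was 0.00745, also below the preset. This list shares 5 genes with the germ cell list and 2, rhi and wde, with the heterochromatin list.

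Meiosis genes followed, with 14 of 27 higher, 1 lower and 12 neither, and the same counts adjusted over the list alone. The synaptonemal complex gene c(3)G had 2615 ± 538 in GSC and 98.7 ± 27 in Kc (log2 fold 4.28), and the checkpoint kinase gene lok had 5372 ± 503 against 598.6 ± 95.4 (3.10). The cohesion gene ord (4.17) and hdm (3.09) also rose, whereas png, a kinase gene of the egg-to-embryo transition, fell by 2.21 on the log2 scale. The median was 1.04 (camera adjusted p = 0.000315). The call was lost with an estimated correlation (adjusted p = 0.124), in a range of 4.41e-05 to 0.124.

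Of 29 genes of maternal RNA-protein particles, 12 rose, 3 fell and 14 passed neither way, and the counts were the same adjusted over the list alone. The RNA-binding protein genes orb, Rbp9 (log2 fold 2.93) and stau (2.42) rose with nanos, while Fmr1, the fly counterpart of the fragile X gene, fell by 2.39 on the log2 scale. A second probe set of Rbp9 was not called (-0.52). The median was 0.53 (camera adjusted p = 0.00845), with adjusted p = 0.558 with an estimated correlation, in a range of 0.00277 to 0.558. The list shares 5 genes with the germ cell list and 1 with the piRNA list, and without shared genes its median was 0.39 and its adjusted p 0.268.

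Polycomb and Trithorax group genes, which keep developmental genes silent or active through chromatin, rose in 15 of 28 cases and fell in 0, with 13 neither and the same counts adjusted over the list alone. The Polycomb complex gene Psc had 1520 ± 128 in GSC and 165 ± 50.8 in Kc (log2 fold 2.97), and the histone demethylase gene Utx had 1014 ± 115 against 114 ± 47.3 (2.83). corto (2.49) and Asx (2.11) followed. The median was 1.18 (camera adjusted p = 0.00047), with adjusted p = 0.244 with an estimated correlation, in a range of 0.000147 to 0.244.

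**Figure D2:**
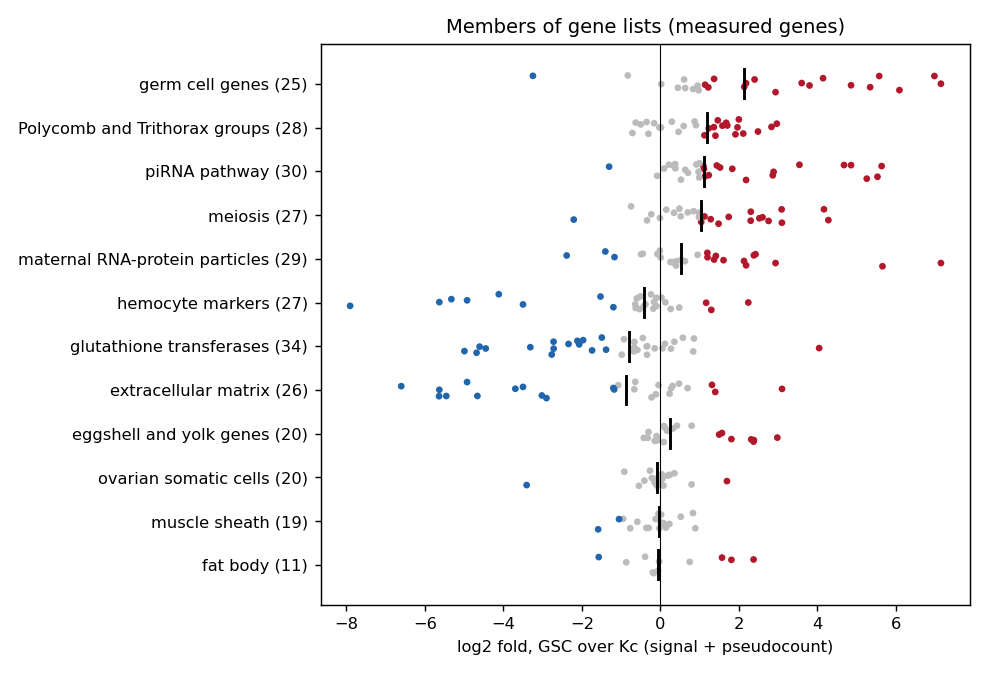
Log2 fold of GSC over Kc (horizontal) for each measured member of 12 lists, 1 point per gene, with genes higher in GSC in red, lower in blue and not called in grey, and a black bar at the list's median. The medians run from 2.13 for germ cell genes to -0.87 for the extracellular matrix among the 8 shifted lists, which stand above the 4 lists of markers of other cell types.

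Extracellular matrix genes were lower in GSC by the test with the preset correlation, a call lost with an estimated correlation and without shared genes. The list shares 5 genes with the hemocyte list and 4 with the cell adhesion list. Of 26 measured, 12 fell, 3 rose and 11 passed neither way, and 13 fell adjusted over the list alone. LanB2 had 44.4 ± 31.1 in GSC and 7660 ± 1240 in Kc, and SPARC, a collagen-binding matrix protein gene, had 336 ± 94.9 against 16190 ± 3140 (log2 fold -5.45). The lysyl oxidase gene Loxl1 rose (3.10), as did the perlecan gene trol (1.40) and the laminin gene wb (1.31), which were named after their values were seen, and the collagen IV gene Col4a1 was below the fold minimum at -0.64 ± 0.175. The median was -0.87 (camera adjusted p = 0.000552), with adjusted p = 0.114 with an estimated correlation, in a range of 4.47e-08 to 0.114. The estimated correlation was -0.035, below the preset. Without shared genes, chosen after the data were seen, the median was -0.23 (adjusted p = 0.072).

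Hemocyte markers shared 5 genes with the matrix list. Of 27 measured, 8 fell, 3 rose and 16 passed neither way, with the same counts adjusted over the list alone. Besides Hml and Pxn, the receptor tyrosine kinase gene Pvr (log2 fold -5.32), Glt (-4.92) and the GATA factor gene srp fell, the last from 1682 ± 504 in Kc to 59 ± 14.6 in GSC (-4.12). The prophenoloxidase gene PPO3 rose by 2.24. The median was -0.42 (camera adjusted p = 0.00276), with adjusted p = 0.124 with an estimated correlation, in a range of 2.09e-05 to 0.165. The estimated correlation was -0.00531, below the preset. Without shared genes, chosen after the data were seen, the hemocyte list had a median of -0.21 (adjusted p = 0.165), and its shift was not called either.

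Glutathione transferases, which conjugate glutathione to toxic compounds, were the third list lower in GSC, a call lost with an estimated correlation. Of 34 measured, 15 fell, 1 rose and 18 passed neither way, with the same counts adjusted over the list alone. GstD3 had 269 ± 55.8 in GSC and 9619 ± 432 in Kc (log2 fold -4.99), GstO3 fell by 4.68 and GstE6 by 4.60, while GstS1 had 4101 ± 394 against 214 ± 38.2 (4.04). Many of these genes are close relatives, and how far their probe sets tell them apart was not tested. The median was -0.80 (camera adjusted p = 3.23e-06), with adjusted p = 0.052 with an estimated correlation, in a range of 3.16e-09 to 0.052. The estimated correlation was -0.000846, below the preset. Of 83 cytochrome P450 genes 9 rose and 9 fell (adjusted p = 0.433), 8 and 9 adjusted over the list alone. The largest was Cyp12d1-d (-4.98). The list was taken by symbol pattern and its 83 genes and its test include Cyp1 and Cyp40, which are cyclophilin genes and were not called.

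The control transcripts of the array moved with the groups. The ratio of the 3' to the 5' probe set of actin was 4.58 ± 0.313 on the GSC arrays and 1.85 ± 0.0789 on the Kc arrays (SD, n = 3; exact permutation test, two-sided p = 0.1, the smallest that 3 against 3 arrays can give). It was 5.23 ± 0.764 against 3.62 ± 0.265 for GAPDH and 6.05 ± 0.916 against 3.61 ± 0.296 for eIF-4a, with the same p. All 3 GSC arrays lay above all Kc arrays for each of the 3 transcripts. This difference accompanies every list above, higher or lower.

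BMP signals from the niche maintain germline stem cells, and 8 of 18 measured BMP pathway genes rose, 4 fell and 6 passed neither way (5 fell adjusted over the list alone). The signal transducer gene Mad had 949 ± 211 in GSC and 262 ± 65.6 in Kc (log2 fold 1.72), the receptor gene sax rose by 2.20 and the activin branch transducer gene Smox by 2.26. The ligand genes daw (-2.66) and gbb (-2.39) fell. The inhibitor gene Dad fell by 1.11 (adjusted p = 0.0133), a call that was lost without Kc 2 (adjusted p = 0.056, in a range of 0.00561 to 0.148 over the alternatives), with hybridisation control scaling (-0.80) and with the pseudocount at the median (-0.59). The receptor gene tkv has 2 probe sets that differ: the one with the higher mean log2 value had a log2 fold of 0.61 (adjusted p = 0.0489, below the fold minimum) and the other 3.17 (adjusted p = 1.5e-06). The gene was called with the mean over its probe sets (1.89) and with hybridisation control scaling (1.02). The list as a whole was not shifted (adjusted p = 0.631).

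In the JAK-STAT pathway 3 of 12 genes rose and 3 fell (adjusted p = 0.831). The receptor gene dome had 1743 ± 21.6 against 721 ± 98.8 (log2 fold 1.24), which the mean over its probe sets left below the minimum (0.79), the repressor gene zfh1 fell by 3.41, and Stat92E had 0.36 ± 0.157 and was not called. In the Notch pathway 3 of 15 rose and 2 fell (adjusted p = 0.631). The ligand gene Delta (1.97) and the co-repressor gene H (1.68) rose, and the fucosyltransferase gene O-fut1 fell by 2.30. The counts of both pathways were the same adjusted over the list alone.

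**Figure D3:**
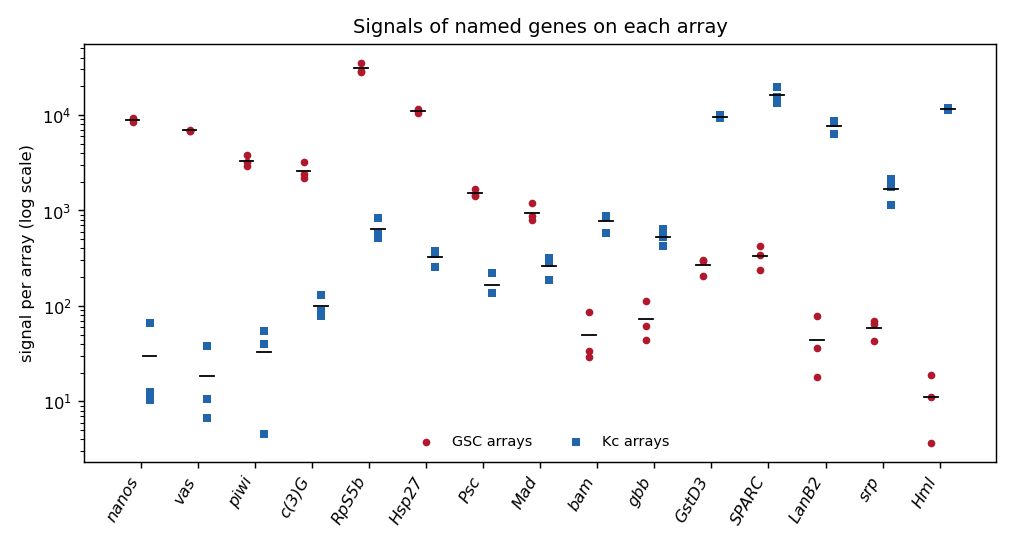
Signal of 15 genes on each array (vertical, log scale), with GSC arrays as red circles, Kc arrays as blue squares and a black bar at the mean of each group of 3. nanos lies at 8369 or higher on all GSC arrays and at 66.2 or lower on all Kc arrays, and Hml at 18.7 or lower on GSC arrays.

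Genes of other cells that an ovary preparation could hold were looked at beside these groups. Of 20 eggshell and yolk genes, 7 rose and 0 fell (adjusted p = 0.124; adjusted p = 0.0356 and a median of 1.53 with dim probe sets left out, in a range of 0.0356 to 0.558 over the camera alternatives). The filter on dim probe sets uses the mean over all 6 arrays. It can keep members bright only in GSC and drop members dim in both groups, which by itself can raise the median. The protease gene ndl had 534 ± 28.9 in GSC and 36.8 ± 21.5 in Kc (log2 fold 2.98), fs(1)N rose by 2.38, the yolk protein gene Yp3 had 458 ± 133 against 55.8 ± 12.1 (2.37) and the vitelline membrane gene Vm26Aa 795 ± 110 against 137 ± 65.7 (2.31). Yp1 and Yp2 rose by 1.81 and 1.57, and these 3 yolk protein genes are the 3 that rose of 11 fat body genes, where 1 fell (Lsd-2, -1.57; adjusted p = 0.978). Of 20 genes of ovarian somatic cells 1 rose (peb, 1.70, below the fold minimum at 0.74 with the pseudocount at the median) and 1 fell (zfh1; adjusted p = 0.631), of 19 muscle sheath genes 0 rose and 2 fell, both actin genes (adjusted p = 0.445), of 23 spermatocyte genes 2 rose and 1 fell (adjusted p = 0.834), and of 17 neuronal genes 2 rose and 0 fell (adjusted p = 0.631). Adjusted over the list alone, 1 neuronal gene rose and the other counts of this paragraph were the same. How far the probe sets of the 2 actin genes tell them from other actin genes was not tested.

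Of 39 mitosis genes 12 rose and 2 fell (adjusted p = 0.0689), a shift called with quantile normalization (adjusted p = 0.0356), the mean over probe sets (0.0432) and hybridisation control scaling (0.0263), in a range of 0.0263 to 0.244 over the camera alternatives. The list shares 4 genes with the meiosis list, twe and cort among them. The condensin gene SMC2 had 3613 ± 146 in GSC against 1039 ± 234 in Kc (log2 fold 1.78), the meiotic phosphatase gene twe rose by 1.74, the centromere gene Cenp-C by 1.54, and the kinesin gene Klp10A fell by 1.27. The other probe sets of Cenp-C had log2 folds of -0.95 and 0.54, and its call ended with the mean over probe sets (0.38). The call of Klp10A ended with hybridisation control scaling (-0.84). CycB was below the fold minimum at 0.38 ± 0.0961. Of 41 DNA replication genes 2 rose and 1 fell (adjusted p = 0.686), and CycE had 2038 ± 603 against 549 ± 166 (1.82). Of 18 apoptosis genes 4 rose and 1 fell (adjusted p = 0.448), with the receptor gene wgn at -3.64 and morgue at 2.63. Adjusted over the list alone, these counts were the same.

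The ribosomal protein list had a camera adjusted p of 0.373, 0.0116 with quantile normalization and 0.0416 with hybridisation control scaling (range 0.0116 to 0.851). Of its 92 genes 37 were measured, and these were mostly alike, with 4 exceptions. All 4 rose and are paralogs: RpS5b (log2 fold 5.54), RpL22-like at 1774 ± 63.3 against 23.4 ± 5.36 (4.89), RpS10a (4.46) and RpS19b at 8636 ± 641 against 2165 ± 131 (1.98). Other paralogs in the list were not called, among them, named after their values were seen, RpL37-2 (0.96), RpS28a (0.27), RpL7-like (-0.08) and RpL10Aa (-0.50). Of 64 mitochondrial ribosomal protein genes 2 rose and 1 fell (adjusted p = 0.997), and of 39 proteasome genes 1 rose, Rpn6 (1.26), and 0 fell (adjusted p = 0.14). Adjusted over the list alone, these counts were the same.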

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

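The 2 tests of the array's 3' and 5' probe sets in this part were chosen after the values were seen.

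Probe sets for array control transcripts lie outside the comparison of genes, and those of 3 transcripts gave a signal that set the groups apart. The log2 ratio of 3' to 5' signal was higher in GSC than in Kc by 1.31 for actin, 0.524 for GAPDH and 0.738 for eIF-4a. A candidate explanation is labelled RNA with less 5' sequence in the GSC preparations, which would put the fold of each middle probe set between those at the ends. It lay there for actin and eIF-4a, and for GAPDH it lay outside by 0.048 on the log2 scale, and since the rule was set with these folds in view it decides nothing and the explanation stays open. Whether lower calls come from probe sets toward the 5' end of their transcript cannot be told apart from a lower transcript level, because probe positions were not used here. Of the 1132 lower probe sets, 370 changed by no more than the actin ratio did. The 5' probe sets had larger log2 folds for actin (-1.585) and eIF-4a (-1.547). The count therefore sets no limit on what less 5' sequence could give. A difference between the cell types in the control transcripts themselves stays open and untested.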

How the results depend on the processing

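The tests of hybridisation control scaling, lists without shared genes and brighter probe sets were chosen after the data were seen. The 1633 higher and 1132 lower probe sets became 956 and 734 with the pseudocount at the median, 2811 and 2002 with no fold minimum, 395 and 375 with a fold of at least 4, both by construction, and 2821 and 688 with hybridisation control scaling. A larger pseudocount shrinks every fold, and for the hybridisation controls the cause was not tested. Leaving out 1 array gave 1563 to 1633 higher and 1094 to 1131 lower, and other alternatives stayed within 1.5 times. The 5 lists up and 3 down became 0 and 0 by camera with an estimated correlation (4 and 3 at an unadjusted p under 0.05), 21 and 9 by fry, which asks a different question, and 4 and 1 without shared genes, where the lists that lost the call were smaller and had medians nearer 0. The estimated correlation lay below the preset 0.01 for germ cell (-0.0122), piRNA (0.00745), glutathione transferase (-0.000846), matrix (-0.035) and hemocyte (-0.00531) lists. It lay above 0.01 for meiosis (0.0196), Polycomb and Trithorax (0.0615) and maternal particle (0.0927) lists. Where it lay below, the lost call does not show that the members vary together. Every other alternative in which lists were tested called 5 to 7 up and 3 down, with 5 and 3 whichever array was left out. Lists were not tested with the other fold minimums, with treat or with brighter probe sets. Of the 153 called named genes, 25 lost the call in at least 1 of 16 alternatives and 0 reversed. Replicate numbers did not pair the samples: deviations of same-numbered arrays correlated at -0.03, 0.036 and -0.007. With the replicate block, 1619 probe sets were higher and 1120 lower, and no list changed its call. Without stated detection calls, how far the dimmest signals lie above background is not known.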

Other observations

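The tests of heat-shock genes and of the 10 splits were chosen after the results were seen, and the tests of neighbouring genes were set before.

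Among 18 heat shock and stress genes 4 rose and 3 fell (camera adjusted p = 0.631), and the small chaperone gene Hsp27 had 11030 ± 464 in GSC against 328 ± 62.8 in Kc (SD, n = 3 each), a log2 fold of 4.93 ± 0.139. Of 12 tubulins and actins 2 rose and 4 fell (adjusted p = 0.469), with the maternal gene gammaTub37C up by 3.27 on its brighter probe set, the other being at -0.11 and not called, and betaTub97EF at -4.18. Of 11 glycolysis genes 1 rose and 3 fell (0.275), and the aldolase gene Ald1 had 146 ± 99.4 against 5604 ± 506 (-5.06). Of 25 lipid and sterol genes 5 rose and 6 fell (0.395), led by the sterol carrier gene Npc2a (-4.61) and the acyl-CoA synthetase gene bgm (3.32). Of 29 adhesion genes 8 rose and 4 fell (0.14), 5 adjusted over the list alone, with Nrg (3.39) up, cora at -2.86, and ed at 3.98 on its brightest probe set and 1.75, 0.91 and 0.69 on the others, of which the first was called. Of 32 innate immunity genes 6 rose and 3 fell (0.851), with the receptor gene Tl up by 2.78 and its ligand gene spz at -4.18. Unless given, counts adjusted over the list alone were the same.

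Of 63 oxidative phosphorylation genes 4 rose and 2 fell (adjusted p = 0.786), and the cytochrome c1 gene Cyt-c1 fell by 3.00 while its paralog Cyt-c1L rose by 2.77. Of 44 translation factors 7 rose and 3 fell (0.978), with eIF4G2 at 6294 ± 1010 against 468 ± 128 (3.67). In 27 pairs of a variant and its partner, formed by symbol after the values were seen from the ribosomal protein, proteasome, oxidative phosphorylation and translation factor lists, 3 variants rose, and in 2 of these pairs the partner fell, Cyt-c1 and eIF3f1 (-1.73). The partner of eIF4G2, eIF4G1, was at 0.99, below the fold minimum. In 1 pair the partner rose, ATPsynbeta (2.26), with its variant at 0.06. The only ribosomal pair was RpLP0-like and RpLP0, so RpS5b, RpL22-like, RpS10a and RpS19b were not among the pairs. eIF4G1, RpLP0-like and RpLP0 are named outside the rule. Among the remaining lists, 4 of 23 ecdysone response genes rose and 4 fell (0.631), 4 of 21 heterochromatin genes rose and 1 fell (0.631), 3 of 8 homeotic genes rose and 1 fell (0.639), 1 of 8 dosage compensation genes rose (0.373), 1 of 10 spectrosome and fusome genes rose, hts at 1349 ± 4.22 against 19.4 ± 9.63, and 1 fell (0.794), 1 of 72 cuticle genes rose and 1 fell (0.632; 1 and 0 adjusted over the list alone), and 2 of 80 odorant and gustatory receptor genes rose (0.978). The median, the mean and the direction of the test differed in sign only among lists that were not called: heat shock, tubulins and actins, JAK-STAT, ecdysone response, homeotic, spectrosome and fusome, spermatocyte, fat body, cuticle, receptor and oxidative phosphorylation genes.

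Hsp27 (4.93), Hsp68 (2.75), Hsp26 (2.37) and Hsf (2.01 on the log2 scale) were higher in GSC, and Hsf, DnaJ-1 and stv were named after their values were seen. A general heat-shock response during cell preparation may have raised Hsp27, Hsp68 and Hsp26. It would also raise the co-chaperone genes DnaJ-1 and stv, whose log2 folds were -0.47 and -0.86, with the higher of their upper limits at -0.19. These folds are against Kc cells, where DnaJ-1 already had a signal of 2582, so a baseline difference can hide a rise and the response cannot be told apart from germline expression. A difference between the cell types stays open and untested. The Hsp70 genes, Hsp22, Hsp23 and Hsp83, named outside the rule, were in the list but not among its 18 measured genes. Their levels are therefore not known here.

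Genes that lie next to each other differed alike. Across 10797 adjacent pairs of measured genes, which are not independent replicates, log2 folds correlated at 0.116, against at most 0.028 in 1000 shuffled orders. Families of related genes that lie side by side could give this, but without the 389 pairs of the same symbol stem the correlation was 0.103. Large blocks of changed copy number in Kc cells could too, but the correlation was smaller at greater distances than between adjacent genes. It was 0.067 at 2 places, 0.058 at 3, 0.022 at 5, 0.032 at 10, 0.018 at 30 and 0.013 at 100. Blocks of fewer than 30 genes, a small part from larger blocks, relatives with unlike symbols and shared regulation of neighbours stay open, the last as an untested hypothesis.

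The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 2765 probe sets, with 1 split reaching that, and the highest of the others called 0 (limma; at most 334 at an unadjusted p under 0.05). For lists, 2 splits reached the real count of 8, the other being GSC 1, GSC 2 and Kc 2 against the rest with 8. Every split but the real one has GSC and Kc arrays on both sides. The difference between GSC and Kc then widens the spread within each side, and part of it remains between the sides. Few probe set calls were therefore foreseeable there, and the mixed splits do not measure what chance would give.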
